A study of Arabidopsis thaliana with 87 samples.

How the data were processed

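Seedlings of Arabidopsis thaliana were 7 days old and, per the labels' protocols, were placed at the end of the light period in darkness, either in argon (hypoxia) or not, for 2 h or 9 h. The groups are named as in the labels: 2NS and 9NS are the controls, 2HS and 9HS the hypoxic seedlings, 1R had 2 h of hypoxia and 1 h of reoxygenation, and 2R had 2 h of each. The 87 samples fell into 35 groups and 11 assays. Nuclear RNA came from affinity-purified nuclei with ribosomal RNA removed. Poly(A)+ RNA was selected with oligo(dT). TRAP RNA was bound to FLAG-tagged ribosomes in a p35S:RPL18-FLAG line and was also selected with oligo(dT). Chromatin immunoprecipitation (ChIP) covered elongating RNA polymerase II phosphorylated at serine 2 (Ser2P), H3K4me3, H3K27me3, H3K9ac, H3K14ac, H2A.Z and the transcription factor HRE2. ATAC-seq measured open chromatin in root tissue, while the other assays used whole seedlings. Lines differed between assays: nuclear RNA, poly(A)+ RNA and ATAC came from a nucleus-tagging line, H2A.Z from a tagged HTA11 line, HRE2 from a line overexpressing a stabilised tagged HRE2, and the other ChIP from Col-0.

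The authors deposited 1 table of RPKM (reads per kilobase of gene and of the library total, scaled) in which each column is the mean over the replicates of a group, per its column names. Per the labels, the tools were Bowtie2, TopHat2 and HOMER on TAIR10; their versions and roles, the read counter and the reads taken as the library total are not given in the sources used here. Strandedness is not given either, so values of overlapping and antisense genes are uncertain, as are those of near-identical copies. The table held 37899 gene identifiers, of which 37746 matched the RefSeq gene table (assembly TAIR10.1). The RefSeq table gave symbols, gene types and the gene lengths used below, among others to recover reads per library. A value was present in all 30 columns for 37684 identifiers, 27327 of them protein-coding, and 572 protein-coding genes were at 0 in every column. In 208 further identifiers, ribosomal RNA among them, only the 4 RNA columns of 9 h held values, so those columns came from another counting run, and 7 identifiers had no value. The authors also deposited 1 peak list per ATAC condition and 1 for HRE2. Per the file headers they came from combined files, and HOMER annotated them against TAIR10 and Araport11. The ATAC lists hold HOMER's deposited peak score; the HRE2 score was 0 for all 4721 peaks and was not used. No input or untagged control is named for HRE2.

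Changes were computed from the authors' means as the log2 ratio of RPKM plus a pseudocount of 1 RPKM, centred on the median gene. Protein-coding genes with a mean of at least 1 RPKM over the columns of an assay were used, and genes at least 2-fold apart were counted. Where the median gene hardly moved, such a change understates that of low genes. Where the median gene moved, centring gives a gene near 0 RPKM a change of the opposite sign by construction, up to 1.75 in poly(A)+ RNA of 9HS against 9NS. A group mean has no spread, so these counts carry no test. For 15 gene lists written before the data were examined, the median change was placed among those of 10000 random lists of the same size, matched on expression in 20 bins. The lists held 51 core hypoxia genes, 25 heat shock genes, 51 cytosolic ribosomal proteins, 27 nuclear photosynthesis genes, 21 circadian clock genes, 19 dark and sugar starvation genes, 10 mitochondrial retrograde and oxidative genes, 23 rapid wound and defence transcription genes (22 in the table), 28 glycolysis and fermentation enzymes (6 shared with the core hypoxia list), 21 auxin and growth genes, 17 cell cycle genes, 14 Polycomb target regulators, 9 root hair, 6 root endodermis and 5 guard cell markers. Spearman correlations were taken across genes.

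A test became possible after the data were seen. A mean of whole reads divided by library totals can take only certain values, and the deposited digits fixed the total reads of each library in 29 columns (all but HRE2) and, for most genes, the whole reads in each library. Genes with several solutions, mostly the abundant ones, were left unresolved, so calls and list tests cover fewer of the genes that were high in a group compared. The recovered libraries carry no replicate number. In 8 simulated columns all reads recovered were right. limma was fitted to these libraries on the same log2 scale, with all groups of an assay in 1 fit, changes centred on the median gene, a trend in the variance and Benjamini-Hochberg adjustment at 0.05, for 28 comparisons. "Rose", "fell" and "called" below refer to this test alone; for unresolved genes the difference in the authors' means is given. Values with ± are limma changes with their standard error. The p-values measure spread between samples that may be technical. In simulated nuclear RNA of 2HS and 2NS, 82.5% of genes changed 4-fold and 7.53% of those changed 2-fold were called. In simulated poly(A)+ RNA of the same groups 100% and 82.1% were, with 6 of 11792 unchanged genes called. Changes were simulated only in genes well above the filter of 1 RPKM, and the spread between libraries was set by hand. These shares therefore do not give the power of the real tests. Gene lists were tested with limma's camera at a preset correlation of 0.01, which called 128 of 370 list and comparison pairs, and with an estimated correlation, which called 34.

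Depth ranged from 1.05 to 16.6 M reads per library in nuclear RNA and from 8.66 to 20.96 M in poly(A)+ RNA. At 1 RPKM a gene of the median length of 2081 bp had 26.9 to 45.3 reads per group in nuclear RNA and 65.2 to 97.9 in poly(A)+ RNA. Intervals given for peaks are 95% Wilson intervals and cover counting error only. Peak overlaps of at least 1 bp were counted with bedtools. A gene's promoter peak was one that HOMER placed at its promoter, which reached 1 kb upstream. HRE2 peaks at genes were compared with Fisher's exact test, two-sided, and with matched random lists.

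Named genes followed a rule written before the data were examined: a panel of 17 genes, the 8 largest changes in each direction with a higher mean of at least 5 RPKM, and the 3 members of each list with the largest change. The rule asked for called genes; as many were unresolved, genes at least 2-fold apart in the means and at least 500 bp long were taken instead, a choice made after the data were seen. Other list members named were chosen after their values were seen. Alternatives tried were a pseudocount of 0.1 RPKM, no filter, quantile normalization, other gene types, columns rescaled to the same protein-coding total (for the means, and for the RNA libraries before the pseudocount and limma, chosen after the data were seen and called rescaled in the text), limma on the compared groups alone, leaving out each library, and other peak overlaps. Motif searches and coordinates of genes were not analysed here for want of a genome. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and bedtools 2.31.1 were used.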

Results

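The series followed Arabidopsis seedlings under hypoxia from chromatin to ribosome-bound RNA, after 2 h and 9 h of hypoxia in darkness and after a short return to air. It held 87 samples in 35 groups and 11 assays: TRAP, nuclear and poly(A)+ RNA, Ser2P and H3K4me3 with 3 samples per group, and ATAC-seq, H3K9ac, H3K14ac, H3K27me3, H2A.Z and HRE2 with 2. Library totals recovered from the deposited values ranged from 1.05 to 16.6 M reads in nuclear RNA, 8.66 to 20.96 M in poly(A)+ RNA and 2.53 to 12.4 M in TRAP RNA. In the ChIP assays other than HRE2 they ranged from 3.55 to 20.2 M. Values below are log2 changes of RPKM + 1 between the authors' means, centred on the median gene. Adjusted p-values are limma's, after Benjamini-Hochberg adjustment, and ± gives the standard error of limma's own estimate. Genes described only as higher or lower in the authors' means could not be tested, as their reads per library could not be resolved, and these means carry no error.

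The comparison of 2HS with 2NS in nuclear RNA asked which genes had more or fewer transcripts in the nucleus after 2 h of hypoxia. PDC1 (pyruvate decarboxylase), ADH1 (alcohol dehydrogenase) and SUS4 (sucrose synthase), enzymes of sugar breakdown and fermentation, were 5.11, 4.66 and 4.39 higher in the authors' means, and ADH1 stood at 146 RPKM against 6.78 RPKM. LBD41, a LOB-domain factor gene, and RBOHD, an NADPH oxidase gene, were 5.10 and 3.81 higher in those means. Rises that passed the test included HRE2 (4.17 ± 0.47, adjusted p = 3.33e-05), an ERF factor of group VII, HRA1 (4.16 ± 0.53, adjusted p = 1.18e-04), a trihelix factor, and PCO2 (3.77 ± 0.44, adjusted p = 4.58e-05), a cysteine oxidase that senses oxygen. The calmodulin-like gene CML38 (4.30 ± 0.45, adjusted p = 1.51e-05) and the hemoglobin gene HB1 (change 2.40, adjusted p = 0.00369) rose too. HRE1, another group VII factor, was 2.21 higher without passing (adjusted p = 0.546).

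Of the core hypoxia genes, 27 of 35 resolved members rose and none fell, and 32 rose when adjusted over the list alone. Their median change was 3.12, above that of all 10000 matched random lists, and the list kept its call with an estimated correlation (adjusted p = 8.60e-06). Heat shock genes had nearly the same median, 3.09, with 9 of 19 resolved members called, all of them higher (16 adjusted over the list alone; adjusted p = 3.27e-04 with an estimated correlation). They included DREB2A (4.13 ± 0.43, adjusted p = 1.51e-05), a heat and drought factor, ROF2 (change 3.64, adjusted p = 1.45e-04), a co-chaperone, and HSFA2 (3.11 ± 0.56, adjusted p = 0.00369), a heat shock factor. The chaperone gene HSP101 was 4.02 higher in the authors' means. Among rapid wound and defence transcription genes 8 of 16 rose (median 2.21; adjusted p = 0.0012 with an estimated correlation), with ZAT12 at 4.29 ± 0.76 (adjusted p = 0.00312), WRKY40 at 3.66 ± 0.45 (adjusted p = 1.24e-04) and WRKY33 at 2.23 ± 0.42 (adjusted p = 0.00597).

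Glycolysis and fermentation enzymes had a median of 1.21, with 2 of 17 resolved members called. The phosphofructokinase genes PFK6 (3.12 ± 0.50, adjusted p = 0.00117) and PFK3 (2.60 ± 0.53, adjusted p = 0.0108) rose. No cytosolic ribosomal protein gene was called among 43 resolved, although their median was 0.55. That list was called at the preset correlation (adjusted p = 5.92e-04) and lost the call with an estimated one (adjusted p = 0.359 with an estimated correlation). Few genes fell: LHY, a morning clock factor, by limma's -1.78 ± 0.39 (adjusted p = 0.0255), and PLDEPSILON, a phospholipase, with a change of -2.89 (adjusted p = 0.0181). CCA1, LHY's close relative, was at -0.64 (adjusted p = 0.884). In all, 1595 genes were at least 2-fold higher and 1355 lower among 15920 in the authors' means, of which 191 and 19 were called. With only these groups in the fit 389 were called. Without centring, as the median gene lay 0.42 lower in 2HS, the counts were 780 higher and 3358 lower. The share of nuclear reads on protein-coding genes, inferred from RPKM and gene length, was 40.5% in 2NS and 33.1% in 2HS.

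Poly(A)+ RNA of the same groups, made from whole cells, asked whether these transcripts also accumulated as polyadenylated RNA. LBD41 and PDC1 were 5.66 and 5.41 higher in the authors' means, HRA1, ADH1 and PCO2 were 4.54, 4.45 and 4.07 higher, and SUS4 was 3.46 higher. LBD41 stood at 401 RPKM against 5.67 RPKM and PDC1 at 157 RPKM against 2.12 RPKM. Tested rises were HRE1 (2.91 ± 0.20, adjusted p = 2.10e-09), HRE2 (2.72 ± 0.29, adjusted p = 7.90e-07), ETR2 (1.62 ± 0.14, adjusted p = 5.35e-08), an ethylene receptor, and ACO1 (2.17 ± 0.18, adjusted p = 3.09e-08), which makes ethylene. AT4G10265 (change 4.79, adjusted p = 2.42e-10), AT4G24110 (4.34 ± 0.30, adjusted p = 2.10e-09) and AT5G66985 (4.16 ± 0.32, adjusted p = 1.16e-08) were among the largest. The median of core hypoxia genes was 2.82, with 18 of 20 resolved members higher (adjusted p = 0.00409 with an estimated correlation).

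Rapid wound and defence genes rose as a list (median 2.03, 9 of 12 resolved; adjusted p = 0.00557 with an estimated correlation), among them ZAT12 (3.10 ± 0.28, adjusted p = 7.06e-08), WRKY40 (2.52 ± 0.31, adjusted p = 5.03e-06) and the cold factor CBF2 (2.04 ± 0.22, adjusted p = 7.26e-07). Glycolysis and fermentation enzymes had a median of 0.41 and 4 of 12 called (adjusted p = 0.0183 with an estimated correlation). For heat shock genes the median was 0.57, with 8 of 22 higher and adjusted p = 0.195 with an estimated correlation. DREB2A (2.21 ± 0.26, adjusted p = 2.69e-06), HSP17.6A (2.04 ± 0.29, adjusted p = 5.79e-05) and MBF1C, a coactivator (1.55 ± 0.29, adjusted p = 5.94e-04), rose, and HSP101 rose by 0.90 ± 0.20 (adjusted p = 0.00376). HSFA2 (0.58 ± 0.30, adjusted p = 0.271), ROF2 (change -0.03, adjusted p = 0.93) and BAG6 (0.14, adjusted p = 0.763) did not pass.

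Auxin and growth genes had a median of -0.50 in poly(A)+ RNA, with 7 of 19 resolved members lower and 1 higher (adjusted p = 0.179 with an estimated correlation). EXPA8, an expansin that loosens cell walls (-1.19 ± 0.18, adjusted p = 1.39e-04), the auxin-induced SAUR22 (change -0.98, adjusted p = 0.00816) and XTH8, a wall enzyme (-0.86, adjusted p = 0.00216), fell, and so did AGP17 (-2.40, adjusted p = 2.87e-08), an arabinogalactan protein gene. Root hair cell markers had a median of -0.64, with 3 of 6 lower, PRP3 (-0.78, adjusted p = 0.00376) among them (adjusted p = 0.195 with an estimated correlation). Of circadian clock genes 2 of 12 fell, LHY (-0.69, adjusted p = 0.0297, or 0.0627 rescaled) and TOC1 (-0.53, adjusted p = 0.0427). The authors' means put 354 genes at least 2-fold higher and 140 lower among 12702; of these 227 and 121 were resolved, and 223 and 119 were called. The median gene lay 0.26 higher in 2HS, and without centring the counts were 530 and 63.

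**Figure D1:**
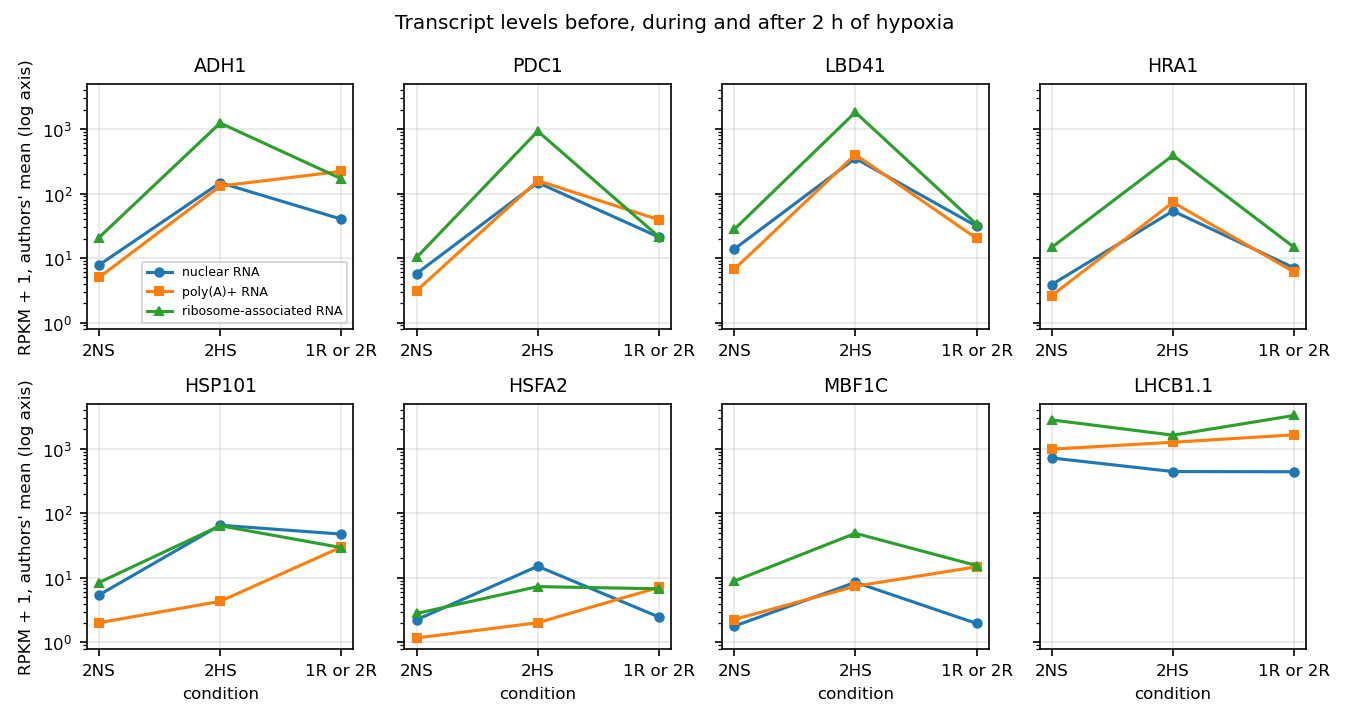
Levels of 8 genes (authors' mean RPKM + 1, log axis) in the nuclear, poly(A)+ and TRAP (labelled ribosome-associated) pools of 2NS, 2HS and the reoxygenated seedlings (1R, or 2R for TRAP). HSP101 in poly(A)+ RNA was at 1.01 RPKM in 2NS, 3.32 RPKM in 2HS and 29.0 RPKM in 1R.

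TRAP RNA, bound to tagged ribosomes, asked which transcripts were on ribosomes after 2 h. PDC1, LBD41, ADH1 and SUS4 were 6.56, 6.10, 5.96 and 5.39 higher in the authors' means, and ADH1 reached 1238 RPKM from 19.8 RPKM. HRE1 (3.97 ± 0.26, adjusted p = 3.96e-07), SRO5 (3.75 ± 0.19, adjusted p = 3.14e-08) and PFK3 (2.94 ± 0.18, adjusted p = 2.02e-07) rose, as did SRO4 (change 5.67, adjusted p = 3.06e-10). In the core hypoxia list, with a median of 3.72, 9 of 11 resolved members rose (adjusted p = 0.022 with an estimated correlation). Heat shock genes had a median of 2.36, with 14 of 18 higher. HSP17.6A (3.41 ± 0.30, adjusted p = 4.89e-06), HSP23.6-MITO, a mitochondrial small chaperone (2.63 ± 0.24, adjusted p = 6.51e-06), MBF1C (2.38 ± 0.36, adjusted p = 4.71e-04) and HSFA2 (1.43 ± 0.29, adjusted p = 0.00355) rose, while ROF2 was at 0.17 (adjusted p = 0.555). The list had adjusted p = 0.0606 with an estimated correlation, as had the rapid wound and defence genes (median 2.36, 6 of 7 higher), in which WRKY46 rose by 3.50 ± 0.21 (adjusted p = 1.75e-07).

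Dark and sugar starvation genes in TRAP RNA had a median of 0.90; SEN1 and ASN1 (asparagine synthetase) were 2.53 and 2.11 higher in the authors' means, and 2 of 4 resolved members were called. Nuclear photosynthesis genes had a median of -0.68, below all matched random lists, with 0 of 27 members resolved, so limma gave neither a call nor an unadjusted p for any. LHCB4.2, of the light-harvesting antenna, was 1.68 lower in the authors' means. Mitochondrial retrograde and oxidative genes had 4 of 8 resolved members lower, NAC017, a factor of that pathway, at -0.61 (adjusted p = 0.0084) among them, and a median of -0.48 (adjusted p = 0.497 with an estimated correlation). CCA1 fell by limma's -1.16 ± 0.19 (adjusted p = 0.00106), UGT74E2, a glycosyltransferase gene, by -2.26 ± 0.30 (adjusted p = 1.16e-04), and IAA29, an auxin response repressor, by -1.18 in the means (adjusted p = 0.00269). Across 15982 genes 951 were at least 2-fold higher and 399 lower, with 571 of 577 and 296 of 297 resolved ones called.

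Differences between assays in the response to 2 h were then tested directly. Heat shock genes changed less in poly(A)+ RNA than in nuclear RNA: the median difference was -2.35, with 2 of 18 resolved members called lower, 9 adjusted over the list alone and adjusted p = 0.026 with an estimated correlation. ROF2 (-3.66 ± 0.63) and the small chaperone gene AT5G51440 (-3.14 ± 0.52) passed, each with adjusted p = 0.0252, and HSP90.1, HSP101 and HSP70 were 3.19, 3.13 and 3.02 apart in the same direction in the authors' means. Core hypoxia genes showed a median difference of -0.15 with 0 of 19 called. Over all genes 4 differed, or 11 rescaled, and leaving out any of 8 of the 12 libraries ended these calls. From poly(A)+ to TRAP RNA the heat shock median difference was 1.46 (3 of 18 higher; adjusted p = 0.216 with an estimated correlation), with HSP23.6-MITO at 2.58 ± 0.41 (adjusted p = 0.00221), HSP17.4 at 2.49 (adjusted p = 0.0255) and AT1G53540 at 2.32 (adjusted p = 0.0385). SRO4 (2.37, adjusted p = 0.00221) rose more in TRAP RNA too, while COR15A, a cold-induced gene, had a difference of -2.31 (adjusted p = 0.0302). In total 201 genes differed, 115 in favour of TRAP RNA and 86 against, from 58 to 712 when 1 library was left out, and 29 and 16 rescaled, without HSP17.4 (adjusted p = 0.0761) and AT1G53540 (adjusted p = 0.102). Protein-coding RPKM totalled 131374 and 182228 in poly(A)+ RNA of 2NS and 2HS, and 475728 and 480301 in TRAP RNA. The pseudocount of 1 RPKM therefore weighs more on low genes in poly(A)+ RNA. Rescaling, done within an assay, does not remove this. The TRAP line differed from the line used for the other RNA, so line and assay are not separated. Near-identical small chaperone genes are uncertain where reads could map to several copies.

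**Figure D2:**
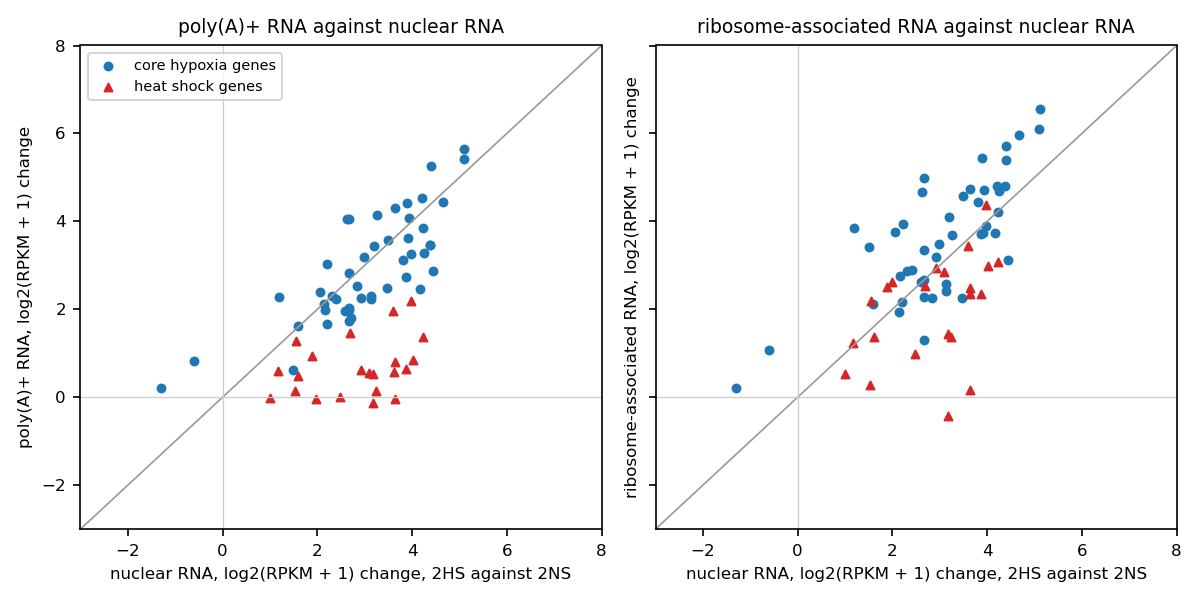
Change from 2NS to 2HS (log2 of RPKM + 1, centred) in poly(A)+ RNA (left) and TRAP RNA (right, labelled ribosome-associated) against the change in nuclear RNA, for core hypoxia genes (blue circles) and heat shock genes (red triangles); the grey line marks equal change. The median change of heat shock genes was 3.09 in nuclear RNA, 0.57 in poly(A)+ RNA and 2.36 in TRAP RNA.

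Ser2P ChIP asked where elongating polymerase differed after 2 h. HSP17.6A, DREB2A, HSP70 and ROF2 were 3.80, 3.45, 3.37 and 3.18 higher in the authors' means, HRA1, LBD41 and CML38 were 3.02, 2.95 and 2.92 higher, and ADH1 and PDC1 1.85 and 1.73 higher. RBCS3B, RBCS1B and RBCS2B, near-identical Rubisco small subunit genes whose values are therefore uncertain, were 1.88, 1.85 and 1.73 lower. Medians were 2.30 for heat shock genes, 1.52 for core hypoxia genes and 0.97 for rapid wound and defence genes, above 10000, 10000 and 9999 of the 10000 matched random lists. limma called 0 genes, with 576 at unadjusted p under 0.05. AT5G37670, a small chaperone gene, was at 2.27 ± 0.45 with adjusted p = 1. Adjusted over the list alone, 5 of 8 resolved core hypoxia genes and 2 of 7 heat shock genes passed (adjusted p = 0.335 with an estimated correlation for each list). In the means 1072 genes were at least 2-fold higher and 215 lower, or 868 and 365 without centring, and the libraries within a group correlated at 0.13 to 0.78 across genes.

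H3K9ac, an acetylation mark of active promoters, asked which genes gained or lost acetylation at 2 h. It rose at HSP17.6A (2.81 ± 0.25, adjusted p = 8.16e-05), AT1G53540 (2.68 ± 0.20, adjusted p = 3.48e-05), PCO1, an oxygen-sensing oxidase (2.38 ± 0.15, adjusted p = 1.98e-05), HRE2 (2.34 ± 0.15, adjusted p = 1.98e-05) and HSFA2 (1.90 ± 0.14, adjusted p = 3.01e-05). ADH1 (1.66 ± 0.16, adjusted p = 1.31e-04), PDC1 (1.54 ± 0.12, adjusted p = 4.36e-05) and PCO2 (1.83 ± 0.14, adjusted p = 3.44e-05) gained it too, as did HRA1 (change 0.94, adjusted p = 0.00474) and LBD41 (0.93, adjusted p = 0.00986). SUS4 (0.64, adjusted p = 0.0853), HRE1 (-0.05, adjusted p = 0.834) and MBF1C (0.12, adjusted p = 0.728) did not pass. Heat shock genes had a median of 1.1005 with 21 of 25 higher, and core hypoxia genes 0.83 with 31 of 48 higher (adjusted p = 0.0799 with an estimated correlation for each). H3K9ac fell at ARR4, a cytokinin response regulator (-1.83, adjusted p = 4.36e-05), BR6OX2, of brassinosteroid synthesis (-1.79, adjusted p = 7.63e-05), and HAT1 (-1.97, adjusted p = 1.57e-04). Nuclear photosynthesis genes had a median of -0.46, with 5 of 27 lower (adjusted p = 0.754 with an estimated correlation). There were 491 genes at least 2-fold higher and 199 lower in the means, with 460 and 185 called.

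H3K14ac was asked the same question at 2 h: 25 genes were at least 2-fold higher and 28 lower, of which 7 and 8 were called. It rose at AT1G53540 (1.32, adjusted p = 0.0367), BBX29 (1.30, adjusted p = 0.0237) and HRE2 (0.70 ± 0.14, adjusted p = 0.0403), and fell at EXPA10, an expansin (-1.09, adjusted p = 0.0217), and PIN7, an auxin carrier (-1.06, adjusted p = 0.0188). ADH1 was at 0.07 (adjusted p = 0.817). Cytosolic ribosomal protein genes had a median of 0.25 with 3 of 51 higher, 14 adjusted over the list alone, and kept their call with an estimated correlation (adjusted p = 0.0392). Leaving out the 2NS library of 8.77 M reads ended every call at 2-fold, as did a fit of these groups alone.

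H2A.Z, a histone variant placed at the start of responsive genes, was lower at several hypoxia genes in 2HS. It fell at LBD41 (-2.14 ± 0.29, adjusted p = 0.00832), CML38 (-2.02 ± 0.22, adjusted p = 0.00207), HRE2 (-1.39, adjusted p = 0.00388), PCO1 (-1.22 ± 0.20, adjusted p = 0.0305) and DREB2A (-1.16 ± 0.16, adjusted p = 0.00832), and at ZAT10, a stress-induced zinc finger factor (-1.21, adjusted p = 0.00908), and PCO2 (-1.02, adjusted p = 0.0351). HRA1 (-1.30, adjusted p = 0.106), PDC1 (-0.62, adjusted p = 0.129), HSP101 (-0.47, adjusted p = 0.41) and ADH1 (-0.24, adjusted p = 0.531) did not pass. It rose at AT1G24996 (1.51, adjusted p = 0.0426). Core hypoxia genes had a median of -0.47 with 10 of 48 lower, 30 adjusted over the list alone (adjusted p = 0.37 with an estimated correlation), and heat shock genes -0.33 with 3 lower (adjusted p = 0.239 with an estimated correlation). Cytosolic ribosomal protein genes had a median of 0.45 and nuclear photosynthesis genes 0.39 with 0 called in each, 8 and 2 adjusted over the list alone (adjusted p = 0.505 with an estimated correlation for each). In the means 87 genes were at least 2-fold higher and 41 lower, with 7 and 22 called. Without the 2HS library of 10.0 M reads 602 genes of that size were called.

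For H3K4me3, a mark of transcribed starts, PCO1, WRKY33 and PCO2 were 1.76, 1.11 and 1.02 higher in the authors' means. ADH1 was at 1.01 ± 0.22 (adjusted p = 0.684), from 6.50 RPKM to 15.2 RPKM. The median of core hypoxia genes was 0.23, above all matched random lists, with 0 of 30 called and 4 higher and 2 lower adjusted over the list alone (adjusted p = 0.844 with an estimated correlation). Cytosolic ribosomal proteins, with a median of -0.16, were called at the preset correlation (adjusted p = 0.00351) but not otherwise (adjusted p = 0.716 with an estimated correlation). limma called 0 genes, with 1313 at unadjusted p under 0.05, against 188 higher and 47 lower by 2-fold in the means.

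For H3K27me3, the Polycomb mark of silenced genes, 2061 genes were at least 2-fold higher and 1303 lower in the means, yet limma called 0, with 1649 at unadjusted p under 0.05. Without the 2HS library of 5.17 M reads, which left 1 library of 2HS, it called 1848 genes of at least 2-fold. The largest differences were at AT5G32619 (3.43), PD1 (3.09) and HTB11 (3.08), and at LCR10 (-2.90) and AGP14 (-2.73), each with adjusted p = 0.767. Polycomb target regulators had a median of -0.17 with 0 of 13 called, and no list was called. With a filter of 20 RPKM in place of 1, 177 genes were 2-fold apart.

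After 9 h of hypoxia the same question was asked of nuclear RNA, against 9NS. PDC1, ADH1, SUS4 and LBD41 were 6.41, 5.60, 5.38 and 5.25 higher in the authors' means, and SUS1, another sucrose synthase, 5.19 higher. PDC1 stood at 409 RPKM against 3.78 RPKM. HRA1 (4.52 ± 0.54, adjusted p = 7.96e-05), CML38 (3.92 ± 0.45, adjusted p = 7.50e-05), HB1 (3.82 ± 0.44, adjusted p = 7.50e-05) and PCO2 (3.76 ± 0.45, adjusted p = 7.96e-05) rose, and so did HRE2 (change 1.99, adjusted p = 0.0117). Of core hypoxia genes, 23 of 31 resolved members rose (median 2.83; adjusted p = 1.01e-04 with an estimated correlation). Heat shock genes had a median of 2.14 with 7 of 19 higher (adjusted p = 0.00654 with an estimated correlation), HSP17.6A at 4.16 ± 0.51 (adjusted p = 9.14e-05) and DREB2A at 3.12 ± 0.43 (adjusted p = 2.68e-04). Glycolysis and fermentation enzymes had 5 of 14 higher (median 1.64; adjusted p = 0.00168 with an estimated correlation) and cytosolic ribosomal proteins 3 of 33, with 11 adjusted over the list alone (median 1.06; adjusted p = 0.0487 with an estimated correlation).

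Among circadian clock genes 3 of 14 resolved members rose and 2 fell in nuclear RNA at 9 h, with a median of -0.82 while the list test pointed up (adjusted p = 0.859 with an estimated correlation). LNK2 and CCA1 were 5.55 and 5.17 lower in the authors' means, and LNK4 (AT5G06980; -4.87, adjusted p = 9.14e-05) and LNK3 (AT3G12320; -4.10, adjusted p = 2.22e-04), their partners in the clock, fell. TOC1, an evening clock gene, rose by 2.36 ± 0.42 (adjusted p = 0.00232), and PRR5 rose (2.61, adjusted p = 0.00428). Of auxin and growth genes 9 of 17 fell and 1 rose (median -2.54; adjusted p = 0.00867 with an estimated correlation): IAA29 by limma's -4.56 ± 0.69 (adjusted p = 5.39e-04), EXPA8 (-3.13, adjusted p = 0.00108) and SAUR22 (-3.02, adjusted p = 0.0085). HFR1, a shade and darkness factor, fell (-4.09, adjusted p = 4.45e-04). Dark and sugar starvation genes had a median of -0.84 (adjusted p = 0.0339 with an estimated correlation), with DIN2 at -2.56 (adjusted p = 0.0316, or 0.106 rescaled) and ASN1 3.37 lower in the authors' means. There were 2077 genes at least 2-fold higher and 1983 lower in the means, with 429 of 1792 and 247 of 1822 resolved ones called. With only these groups in the fit the calls of that size numbered 1530, and rescaled 438.

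In poly(A)+ RNA at 9 h, PDC1, ADH1 and LBD41 were 4.94, 4.89 and 4.24 higher in the authors' means. CML38 (4.28 ± 0.29, adjusted p = 3.16e-09), HRA1 (3.78 ± 0.20, adjusted p = 3.08e-10), SUS1 (3.53 ± 0.20, adjusted p = 1.49e-09), SUS4 (3.36 ± 0.27, adjusted p = 3.18e-08) and PCO2 (3.03 ± 0.20, adjusted p = 2.08e-09) rose. Medians were 2.52 for core hypoxia genes, with 35 of 37 higher, and 1.52 for rapid wound and defence genes, with 15 of 16 (adjusted p = 0.0569 with an estimated correlation for each). Heat shock genes had 1.93 with 19 of 23 (adjusted p = 0.152 with an estimated correlation), and HSP101 rose by 1.98 ± 0.20 (adjusted p = 3.92e-07). Rescaled, which left a median shift of 0.11 and so little of the lift that centring gives to genes near 0, HSP101 rose by 2.43 ± 0.22 (adjusted p = 1.92e-07) and HSFA2 by 1.33 ± 0.31 (adjusted p = 0.00265). The antenna genes LHCB2.1, LHCB3 and LHCB1.1 were 5.57, 4.20 and 3.75 lower in the authors' means, LHCB1.1 from 8553 RPKM to 188 RPKM. LHCB1 and LHCB2 copies are near-identical and uncertain. The median of nuclear photosynthesis genes was -1.85, with 0 resolved. Auxin and growth genes had 13 of 15 lower and 1 higher (median -2.20; adjusted p = 0.0569 with an estimated correlation), with SAUR22 (-2.48, adjusted p = 1.42e-08), HB-2 (-2.19, adjusted p = 1.21e-08) and IAA29 (-2.20, adjusted p = 9.92e-07).

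Circadian clock genes in the same comparison had a negative median, -1.01, or -0.84 rescaled. Of 6 resolved members, all below 5 RPKM in 9HS, 5 rose in the rescaled libraries, BOA by 1.38 ± 0.22 (adjusted p = 5.92e-05) and TOC1 by 1.25 ± 0.16 (adjusted p = 7.68e-06), and the list test pointed up (adjusted p = 0.0202 with an estimated correlation, or 0.0569 as deposited). The unresolved CCA1 was 2.54 lower in the authors' means. From RPKM and gene length, protein-coding genes were inferred to take 10.2% of the reads in poly(A)+ RNA of 9HS and 64.4% in 9NS. The median gene lay 1.75 lower in 9HS: centred, 668 genes were at least 2-fold higher and 1120 lower, without centring 43 and 11381, and with columns rescaled to the same protein-coding total 694 and 863. Of the resolved genes 2-fold apart after centring, 99.7% were called. Resolved were 637 of the 668 higher genes and 492 of the 1120 lower ones, so the calls and list tests leave out more of the lower genes. At any size 2180 genes were called higher and 2143 lower, of which 1071 and 1179 were called in the same direction rescaled. Between 2 h and 9 h, which share no library, 217 genes were higher in each (18.6 if independent) and 80 lower (12.3 if independent).

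H3K9ac at 9 h rose at all 25 heat shock genes (median 2.18; adjusted p = 0.188 with an estimated correlation): HSP17.6A by 3.85 ± 0.25 (adjusted p = 2.86e-06), HSFA2 by 3.26 ± 0.14 (adjusted p = 7.25e-07) and HSP101 by 1.96 ± 0.12 (adjusted p = 2.43e-06). It rose at HRE2 (2.86 ± 0.15, adjusted p = 1.27e-06), PDC1 (1.80, adjusted p = 3.78e-06) and ADH1 (1.59, adjusted p = 3.20e-05), and fell at LBD41 (-0.99 ± 0.20, adjusted p = 0.00294), whose transcripts were higher. Of 48 core hypoxia genes 33 rose and 6 fell (median 0.74; adjusted p = 0.188 with an estimated correlation). All 27 nuclear photosynthesis genes fell (median -1.45; adjusted p = 0.217 with an estimated correlation), with RBCS1A at -2.47 ± 0.17 (adjusted p = 3.85e-06). Dark and sugar starvation genes had 14 of 19 lower and auxin and growth genes 15 of 21 lower with 3 higher (medians -0.76 and -0.92; adjusted p = 0.217 with an estimated correlation for each), ASN1 (-1.33, adjusted p = 7.24e-05), the autophagy gene ATG8E (-1.66, adjusted p = 2.31e-05) and EXPA8 (-2.47, adjusted p = 3.07e-06) among them. Genes 2-fold apart numbered 1134 higher and 1152 lower, with 1120 and 1128 called, and 347 were higher at 2 h and 9 h alike (21.02 if independent).

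H3K14ac at 9 h rose at heat shock genes (median 0.95, 21 of 25; adjusted p = 0.0277 with an estimated correlation), with HSP17.6II at 2.04 ± 0.14 (adjusted p = 6.91e-05), and at CBF4, a drought and abscisic acid induced factor (2.48, adjusted p = 1.49e-04) and HRE2 (1.39, adjusted p = 2.00e-04). Cytosolic ribosomal protein genes had 31 of 51 higher (median 0.44; adjusted p = 0.0277 with an estimated correlation), RPS6A among them (0.65, adjusted p = 0.00773), while their H3K9ac had a median of -0.21 with 16 lower and 2 higher (adjusted p = 0.671 with an estimated correlation). ADH1 (-0.07, adjusted p = 0.666) and PDC1 (0.05, adjusted p = 0.852) were near 0, and LBD41 fell by limma's -1.26 ± 0.19 (adjusted p = 9.54e-04). The means gave 538 genes at least 2-fold higher and 96 lower, 367 and 160 without centring. Of these 534 and 81 were called.

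**Figure D3:**
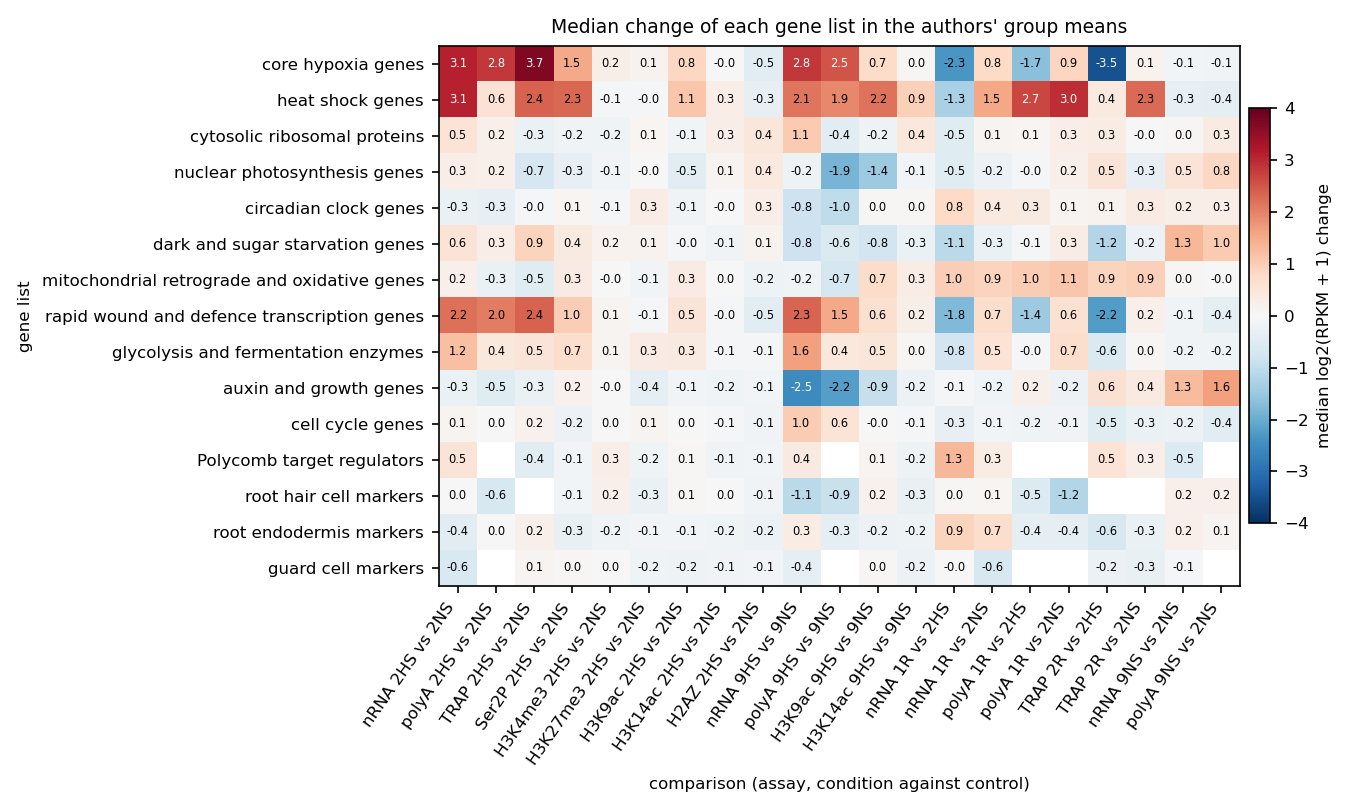
Median log2 change (RPKM + 1, centred, authors' means) of 15 gene lists in 21 comparisons; blank cells had too few measured members. Core hypoxia genes ranged from 3.72 in TRAP RNA of 2HS against 2NS to -3.47 in TRAP RNA of 2R against 2HS.

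Controls also differed between 2 h and 9 h of darkness. In nuclear RNA, LNK2, ASN1, PRR7 and CCA1 were 6.14, 4.30, 4.11 and 4.09 higher in the authors' means of 9NS. There LNK4 (4.63, adjusted p = 0.00146) and LNK3 (4.17, adjusted p = 0.00181) rose, and COL9 (-3.45) and JMJD5 (-3.02), each with adjusted p = 0.00146, fell. In poly(A)+ RNA, HB-2 rose by 2.56 ± 0.18 (adjusted p = 1.44e-08), IAA29 (2.37, adjusted p = 2.41e-06) and SAUR22 (2.21, adjusted p = 3.21e-07) rose, and the evening genes ELF4 (-2.27 ± 0.22, adjusted p = 5.05e-07) and TOC1 (-1.53, adjusted p = 1.44e-06) fell. Auxin and growth genes had medians of 1.27 in nuclear RNA (0 of 17 called, 6 adjusted over the list alone; adjusted p = 0.00488 with an estimated correlation) and 1.64 in poly(A)+ RNA (11 of 14 higher, 1 lower; adjusted p = 0.0374 with an estimated correlation). Dark and sugar starvation genes had medians of 1.32 and 1.03, and nuclear photosynthesis genes in poly(A)+ RNA 0.82 with 0 resolved. The circadian clock list had a median of 0.26 in poly(A)+ RNA although 5 of 5 resolved members fell (adjusted p = 0.0106 with an estimated correlation). The unresolved CCA1 was 3.22 higher there in the authors' means. Of the genes 2-fold apart in that comparison, 211 of 420 higher and 156 of 192 lower ones were resolved. The list test and the calls thus leave out more of the higher genes. Centring also lowers genes near 0 RPKM here, as the median gene moved by 0.99. Nuclear RNA had 502 genes at least 2-fold higher and 473 lower, 1754 and 108 without centring as the median gene moved by 0.42, and 7 called, or 106 with only these groups in the fit. For poly(A)+ RNA there were 420 and 192, 6280 and 10 without centring as it moved by 0.99, and 826 called higher and 801 lower at any size, or 370 and 415 rescaled. The 9 h columns came from another counting run, so time and run are not separated.

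Whether hypoxia acted differently at 9 h than at 2 h was tested as the difference of the effects, each against its own control. Auxin and growth genes had a lower effect at 9 h in nuclear RNA (median difference -2.40; adjusted p = 0.019 with an estimated correlation), where LNK4 was at -5.22 (adjusted p = 0.0459, or 0.103 rescaled) and LNK2 and CCA1 were 6.20 and 4.53 lower in the means. In poly(A)+ RNA heat shock genes had a median difference of 1.31 with 5 of 22 higher and 1 lower (adjusted p = 0.634 with an estimated correlation), HSP17.4 at 2.78 (adjusted p = 0.00671), and 3 higher rescaled, with HSP17.4 at 2.20 ± 0.55 (adjusted p = 0.0223), and auxin and growth genes -1.57 with 10 of 14 lower (adjusted p = 0.117 with an estimated correlation). For H3K9ac 14 of 25 heat shock genes gained more at 9 h (median 1.01; adjusted p = 0.274 with an estimated correlation), DREB2A by 1.70 (adjusted p = 0.00273), and RBCS1A was at -2.12 (adjusted p = 0.0035). For H3K14ac 5 of 25 heat shock genes did (median 0.89; adjusted p = 0.0314 with an estimated correlation), and CBF4 (2.11, adjusted p = 0.0259) and TCH4, a wall enzyme induced by touch (1.51, adjusted p = 0.0259), differed. At any size 3 genes differed in nuclear RNA, 1584 in poly(A)+ RNA, 1262 in H3K9ac and 43 in H3K14ac. Rescaled, limma called 0 in nuclear RNA, with 748 at unadjusted p under 0.05, and 600 in poly(A)+ RNA. Leaving out 1 library gave 673 to 3125 calls in poly(A)+ RNA. The H3K9ac count moved with the library left out as well, but those fits leave 1 library in a group. Leaving out any of 10 of the 12 libraries ended the calls of at least 2-fold in nuclear RNA, and any of 5 of the 8 ended those in H3K14ac.

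Reoxygenation for 1 h was compared with the end of hypoxia in nuclear RNA. Seedlings of 1R and 2R were harvested later than those of 2HS and 2NS, without an untreated group of the same hour here, so reoxygenation is not separated from time of night or light. PCO2 (-3.61 ± 0.44, adjusted p = 2.07e-04), HRA1 (-3.35 ± 0.53, adjusted p = 0.00158) and CML38 (-3.38, adjusted p = 2.75e-04) fell, and PDC1, SUS4 and ADH1 were 3.27, 2.83 and 2.33 lower in the authors' means. APR1 (3.83, adjusted p = 0.00114) and APR3 (3.45, adjusted p = 4.13e-04), enzymes of sulfate reduction, rose. The core hypoxia list had a median of -2.33, with 21 of 35 lower (adjusted p = 1.98e-04 with an estimated correlation) and heat shock genes -1.29 with 5 of 19 lower (adjusted p = 0.0339 with an estimated correlation). Against 2NS, the co-chaperone ROF2 (3.54 ± 0.49, adjusted p = 0.00469), HSP90.1 (3.07 ± 0.36, adjusted p = 0.00382) and HSP101 (2.95 ± 0.40, adjusted p = 0.0075) were still higher, HSFA2 was at 0.09 (adjusted p = 0.978) and ADH1 at 2.13 ± 0.44 (adjusted p = 0.136). Of 2260 genes at least 2-fold higher and 2135 lower than in 2HS, 95 and 194 were called, or 98 in all with only these groups in the fit and 441 rescaled. Without centring the counts were 4335 and 999, as the median gene lay 0.46 higher in 1R. Against 2NS there were 12 calls, all higher (1 with only these groups in the fit), among 1592 and 1364, and leaving out the 2NS library of 2.22 M reads ended them all.

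Small chaperone genes were the named genes that stood highest in poly(A)+ RNA of 1R against 2HS. AT1G53540, HSP23.6-MITO, HSP17.6II and HSP101 were 4.89, 4.43, 4.34 and 2.19 higher in the authors' means, and HSP17.4 (3.75 ± 0.37, adjusted p = 2.90e-07) and HSFA2 (1.15 ± 0.30, adjusted p = 0.0122) rose. The heat shock list had a median of 2.67 with 7 of 12 higher and 3 lower (adjusted p = 0.404 with an estimated correlation). Mitochondrial retrograde and oxidative genes rose in 5 of 8 (median 1.02; adjusted p = 0.0555 with an estimated correlation), among them UPOX (AT2G21640; 2.36, adjusted p = 1.64e-05) and NAC13 (1.81, adjusted p = 4.10e-08), and the alternative oxidase gene AOX1A was 2.29 higher in the authors' means. LBD41, HRA1 and PDC1 were 4.93, 4.20 and 2.63 lower in those means. AT4G10265 (-4.61, adjusted p = 1.11e-09), HRE1 (-1.45, adjusted p = 6.73e-05) and WRKY33 (-2.04, adjusted p = 4.30e-06) fell, while ADH1 was 0.15 higher and HRE2 at 0.17 (adjusted p = 0.558). Of core hypoxia genes 14 of 20 fell (median -1.68; adjusted p = 0.0555 with an estimated correlation). Against 2NS, heat shock genes had a median of 2.95 with 10 of 12 higher and core hypoxia genes 0.87 with 19 of 35 higher (adjusted p = 0.128 and 0.149 with an estimated correlation). HRE2 was 3.05 ± 0.29 above 2NS (adjusted p = 5.91e-07), LBD41 0.80 ± 0.21 (adjusted p = 0.0172, or 0.0958 rescaled) and HRA1 0.35 (adjusted p = 0.171). Auxin and growth genes against 2NS had a median of -0.23 with 5 of 18 lower and 2 higher, but the list test pointed up (adjusted p = 0.913 with an estimated correlation), and the median was above 0 with a pseudocount of 0.1 RPKM (0.20), with no filter (0.11), after quantile normalization (0.16) and rescaled (0.16).

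Counts for poly(A)+ RNA of 1R were 330 genes at least 2-fold higher and 256 lower than in 2HS, with 213 and 185 called, and 375 and 109 against 2NS, with 195 and 87 called. Without centring they were 1647 and 97, and 4658 and 3, as the median gene lay 0.61 and 0.86 higher in 1R. Protein-coding genes were inferred to take 55.1% of reads in 1R, 34.1% in 2HS and 25.1% in 2NS.

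TRAP RNA asked which transcripts stayed on ribosomes after 2 h of reoxygenation. Compared with 2HS, LBD41, PDC1, SUS4 and ADH1 were 5.94, 5.61, 5.42 and 3.04 lower in the authors' means, HRE1 fell by limma's -3.17 ± 0.26 (adjusted p = 1.98e-06), and WRKY46 fell (-3.56, adjusted p = 1.08e-07). UGT74E2 (3.14 ± 0.30, adjusted p = 6.34e-06), the sulfur-response gene LSU3 (3.21, adjusted p = 1.79e-07) and IAA29 (2.16, adjusted p = 2.64e-05) rose. Of core hypoxia genes, 9 of 11 fell (median -3.47; adjusted p = 0.0402 with an estimated correlation). Auxin and growth genes rose in 9 of 13 (median 0.60; adjusted p = 0.34 with an estimated correlation). Against 2NS, SUS4 (-0.04, adjusted p = 0.895) and LBD41 (0.15, adjusted p = 0.694) were near 0, PDC1 was at 0.93 ± 0.14 (adjusted p = 0.00544) and ADH1 was 2.91 higher in the authors' means. Heat shock genes stayed higher (median 2.27, 12 of 19; adjusted p = 0.0219 with an estimated correlation), HSP23.6-MITO at 4.91 ± 0.24 (adjusted p = 2.38e-07) and HSP101 at 1.67 ± 0.17 (adjusted p = 3.88e-04). Counts were 770 higher and 1182 lower against 2HS (651 and 687 called), or 1228 and 849 without centring. They were 225 higher and 104 lower against 2NS (157 and 74 called), or 302 and 62 without centring; the median gene moved by 0.17 and 0.12. Without the 2R library of 5.10 M reads 135 genes of that size were called against 2NS.

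Open chromatin in roots was compared through the authors' ATAC peak lists, 1 per condition, which allow no test between samples. Promoter peaks at ADH1, LBD41, HRA1 and PDC1 were absent in 2NS and numbered 2, 4, 2 and 2 in 2HS; at ADH1 they lay on chromosome 1 at 28975077 to 28975201 and 28975254 to 28975378 (TAIR10), centred 116 bp upstream and 61 bp downstream of the transcription start. HSP101 and HSFA2 had 0 in 2NS and 1 and 2 in 2HS. In 9NS, a control with a longer list, ADH1, LBD41, HRA1 and PDC1 had 1, 1, 0 and 0 promoter peaks. In 9HS they had 2, 2, 1 and 0. HSP101 and HSFA2 had 0 and 1 in 9NS and 1 and 1 in 9HS. Of the 51 core hypoxia genes, 43.1% had a promoter peak in 2NS, 82.4% in 2HS and 78.4% in 1R, and of the 25 heat shock genes 16.0%, 52.0% and 44.0%. All protein-coding genes went from 21.1% to 39.2% and 50.5%, as the lists grew from 14398 peaks in 2NS to 27219 in 2HS and 38958 in 1R. At 9 h the lists held 27065 peaks in 9NS and 21438 in 9HS, and promoter peaks went from 38.3% to 32.7% of all genes, but from 62.7% to 74.5% of core hypoxia and from 8 to 15 of the 25 heat shock genes. Peaks of 2NS overlapped 47.9% (95% interval 47.3 to 48.5) of those in 2HS, or 75.7% with equal numbers of top-scoring peaks, and 96.0% of 2NS peaks were met by a 2HS peak.

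**Figure D4:**
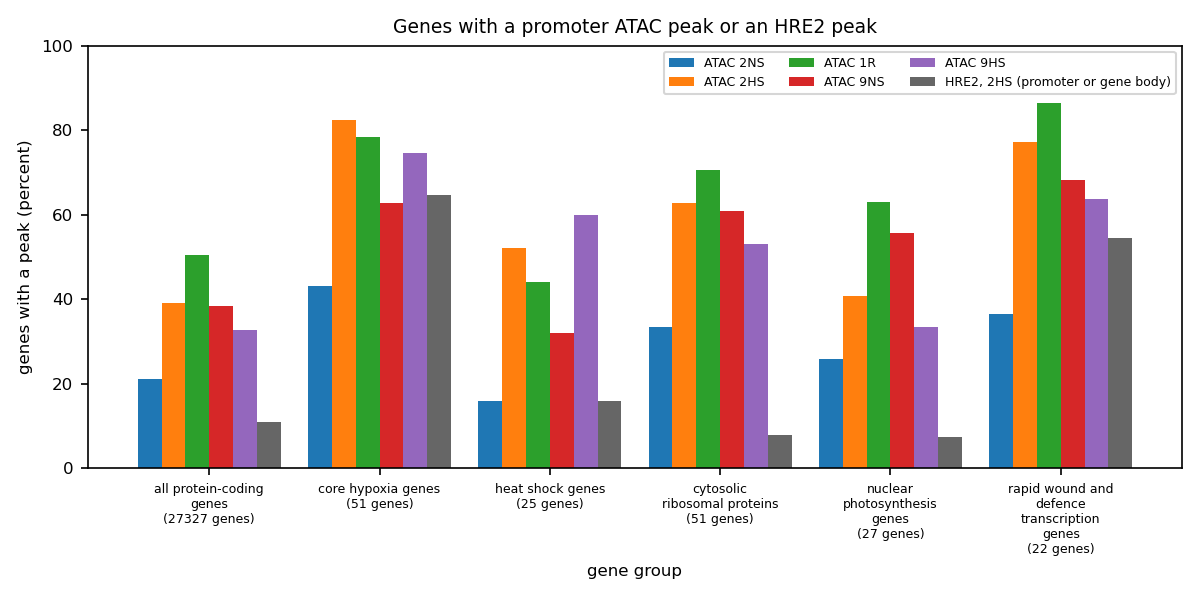
Percent of genes with a promoter ATAC peak in each condition (colours) and with an HRE2 peak in the promoter or gene body (grey), for all protein-coding genes and 5 gene lists. Core hypoxia genes had promoter ATAC peaks at 82.4% in 2HS and HRE2 peaks at 64.7%.

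HRE2 peaks in 2HS, from the line overexpressing a stabilised HRE2, were set beside these genes. At ADH1 a peak lay on chromosome 1 at 28975061 to 28975216 (TAIR10), in the promoter 117 bp upstream of the start and over the ATAC peak there. LBD41 had a promoter peak on chromosome 3 at 538335 to 538490, 286 bp upstream, and another in an exon. SUS4 had its peak on chromosome 3 at 15184086 to 15184241, 58 bp upstream, CML38 on chromosome 1 at 28767779 to 28767934, 144 bp upstream, and WRKY33 on chromosome 2 at 16108071 to 16108226, 87 bp upstream. A peak in the promoter or gene body was found at 64.7% of core hypoxia genes (33 of 51) and 54.5% of rapid wound and defence genes. It was found at 42.1% of dark and sugar starvation genes and 16.0% of heat shock genes, against 10.9% of all protein-coding genes. Within 500 bp upstream alone these shares were 37.3%, 22.7%, 0% and 0%, against 2.43%. Of the 354 genes 2-fold higher in poly(A)+ RNA of 2HS, 32.8% had a peak, against 13.6% of the other tested genes (odds ratio 3.09, Fisher's exact test p = 2.06e-19). Matched random lists of that size had 14.8% on average. Of the 140 lower genes 27.9% had a peak, again above all 10000 matched lists (mean 14.2%). Within 500 bp upstream 15.0% of the 354 higher and 6.4% of the 140 lower genes had one, against 3.2% of the genes not higher. For genes higher in nuclear and TRAP RNA the odds ratios were 1.49 and 2.07. Of the genes lower in nuclear RNA 12.5% had a peak, against 13.1% of those not higher, and of those lower in TRAP RNA 23.6%. Genes are not independent replicates, and no control for this ChIP is named. ATAC peaks of 2HS covered 39.7% (95% interval 38.4 to 41.1) of HRE2 peaks, and 7.56% and 7.35% after the HRE2 peaks were shifted by 5000 bp to either side.

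Finally, changes at 2 h were compared across assays over 11901 genes, which are not independent replicates. Spearman's correlation was 0.516 between poly(A)+ and TRAP RNA, 0.389 between nuclear and poly(A)+ RNA and 0.275 between nuclear and TRAP RNA. Ser2P correlated with H3K9ac at 0.551 and with H2A.Z at -0.389. Libraries within 2NS and 2HS correlated at 0.63 to 0.79 in nuclear RNA and 0.92 to 0.96 in poly(A)+ RNA. The range was 0.92 to 0.97 in TRAP RNA and 0.13 to 0.78 in Ser2P. Such spread lowers a correlation unequally, and lines differed between assays, so the coefficients are not ranked. As limma called 0 genes in Ser2P, its changes here are untested differences between means. Of 349 genes 2-fold higher in poly(A)+ RNA and measured in TRAP RNA, 329 were 2-fold higher there too (23.0 if independent), while 295 genes were higher in nuclear and poly(A)+ RNA (37.1 if independent). H3K9ac and nuclear RNA shared 155 higher genes (24.2 if independent), and 32 of 38 genes with lower H2A.Z had higher Ser2P (1.53 if independent), LBD41, CML38 and DREB2A among them.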

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

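The tests in this part were chosen after the results were seen. Hypoxia differed in its effect between 2 h and 9 h for 3 genes in nuclear RNA, 1584 in poly(A)+ RNA, 1262 in H3K9ac and 43 in H3K14ac. With columns rescaled to the same protein-coding total limma called 0 in nuclear RNA, with 748 at unadjusted p under 0.05, and 600 in poly(A)+ RNA. In nuclear RNA the clock gene LNK4 was at -5.22 (adjusted p = 0.0459, or 0.103 rescaled). The 5.8S ribosomal RNA gene AT2G01020, which only the 9 h columns list, stood at 3235 RPKM in poly(A)+ RNA of 9HS against 1338 RPKM in 9NS.

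Calls were also counted after relabelling libraries across the groups compared, each group then holding libraries of several conditions. With 3 libraries against 3 there were 10 relabellings including the real one, too few for a share under 0.05. In 13 comparisons the real labels alone gave as many calls as were seen (1 of 10), and the highest other relabelling gave 0 calls, or 1 for poly(A)+ RNA of 9NS against 2NS. The real counts were 210 genes in nuclear RNA of 2HS, 1055 in poly(A)+ RNA of 2HS and 3327 in TRAP RNA of 2HS, each against 2NS. For Ser2P and H3K4me3 the real count was 0, which every relabelling reaches by definition. The highest other relabelling gave 0 calls for H3K4me3. For Ser2P it gave 1604, so structure of the samples other than hypoxia is large in Ser2P.

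For differences of effects 100 relabellings were used, the real one included. As many calls as in the real data or more came in 8 of them for the 9 h against the 2 h effect in nuclear RNA (real 3, highest 369) and in 5 for poly(A)+ RNA (real 1584, highest 3473). The same held in 13 for poly(A)+ against nuclear RNA at 2 h (real 4, highest 96), in 6 at 9 h (real 80, highest 554) and in 10 for TRAP against poly(A)+ RNA (real 201, highest 1790). Relabelling a single RNA comparison gave at most 1 call, so relabellings with up to 3473 calls may still carry a hypoxia difference. They therefore do not decide whether chance gives such counts, and chance is not excluded. Rescaled, they were 11 and 4 for poly(A)+ against nuclear RNA at 2 h and 9 h and 45 for TRAP against poly(A)+ RNA.

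Heat shock genes rose less in poly(A)+ RNA than in nuclear RNA after 2 h of hypoxia, by a median of -2.35. Centring had already removed the scaling of a whole column, except where the pseudocount weighs on low genes. The median of -0.15 for core hypoxia genes therefore does not decide on scaling. With a pseudocount of 0.1 RPKM the heat shock median was -2.51. An oligo(dT) selection that misses heat shock transcripts might give the lower poly(A)+ change. Yet TRAP RNA, selected the same way, had a median heat shock change of 2.36, which argues against such a selection. Later entry of the transcripts into the poly(A)+ pool remains open: after 1 h of reoxygenation the list had a median 2.67 above 2HS in poly(A)+ RNA, which may also reflect new transcription in that hour.

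The poly(A)+ RNA column of 9HS was low for most protein-coding genes, which their inferred share of reads, 10.2% in 9HS and 64.4% in 9NS, restates. Whether a larger share of reads outside the listed genes is the source stays open, because what the library totals counted is not given. Dividing by each column's protein-coding total left a median shift of 0.11 in place of -1.75, but a column low for most genes has a low total by construction. Carry-over of ribosomal RNA is a possible source and is open. The 5.8S gene stood 1.27 log2 units higher in 9HS than in 9NS in poly(A)+ RNA. In nuclear RNA it went the other way, from 2866 RPKM in 9NS to 921 RPKM in 9HS. This short RNA does not give the share of all ribosomal RNA. RPKM in poly(A)+ RNA totalled 359491 in 9NS and 59411 in 9HS over all listed genes. Over protein-coding ones it totalled 352715 and 53887. The remaining listed genes, ribosomal RNA among them, thus did not take up the fall in RPKM.

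Many genes differed 2-fold in H3K27me3, and limma called 0 of them. Counting error alone would give 18.2 of the 3364 genes on simulated data, which argues against it as the source. Differences between the libraries within a group fit: with a library of 2NS and a library of 2HS on each side, 4963 and 4677 genes were 2-fold apart in the 2 possible splits, against 4816 for 2HS against 2NS. These counts average log2 values of the recovered libraries, whereas the 3364 come from the authors' means, and without the 2HS library of 5.17 M reads, which left 1 library of 2HS, limma called 1848 genes of at least 2-fold.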

How the results depend on the processing

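The alternatives that use recovered libraries, the 20 RPKM filter and the protein-coding rescaling were chosen after the results were seen. No paired analysis was possible because the deposited columns are means of replicates and the libraries recovered from them carry no replicate number. A replicate block was therefore not run, and ranking HRE2 peaks by score was not possible as all scores are 0. Across the settings, 254 counts of 2-fold genes moved and 151 stayed. Of list medians 77 moved, 16 changed sign and 1897 stayed. Of values of named genes 400 moved, 1 changed sign and 4609 stayed. Each count, limma's calls included, was set against the untested count in the authors' means. Of the 254 moves, 159 came from leaving out a library. A further 22 came from limma on all groups, 22 on the compared groups alone and 15 on rescaled libraries. These moves include the step from an untested count to tested calls, so they do not measure processing alone. The cause of the other moves was not tested.

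With a pseudocount of 0.1 RPKM the genes at least 2-fold apart in 2HS against 2NS numbered 5426 in nuclear RNA, 942 in poly(A)+ RNA, 2148 in TRAP RNA, 530 in H3K4me3, 5237 in H3K27me3, 99 in H3K14ac and 329 in H2A.Z. For 1R they were 6597 and 4844 in nuclear RNA against 2HS and 2NS, and 975 and 803 in poly(A)+ RNA; for TRAP RNA of 2R against 2NS 638, for nuclear RNA of 9NS against 2NS 2083, for the 9 h minus 2 h effect in H3K14ac 463, and for poly(A)+ minus nuclear RNA at 2 h 3358. Counting all gene types gave 772 in H3K4me3, 5514 in H3K27me3, 1101 in H3K9ac, 273 in H3K14ac and 460 in H2A.Z of 2HS, 1159 in H3K14ac of 9HS, and 1770 and 961 for the 9 h minus 2 h effects in H3K9ac and H3K14ac. With a filter of 20 RPKM H3K27me3 had 177.

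With no filter poly(A)+ RNA had 7311 genes in 9HS against 9NS, 904 in 1R against 2NS, 1221 in 9NS against 2NS and 9767 for 9 h minus 2 h, and poly(A)+ minus nuclear RNA had 2973 at 2 h and 10331 at 9 h. Quantile normalization gave 250 in H3K14ac of 9HS, 839 and 191 for 9 h minus 2 h in poly(A)+ RNA and H3K14ac, and 1802 for poly(A)+ minus nuclear RNA at 9 h. After rescaling to the protein-coding total these were 942 for 9 h minus 2 h in poly(A)+ RNA and 1755 for poly(A)+ minus nuclear RNA at 9 h.

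limma's calls of at least 2-fold, with all groups of the assay and then with only the groups compared in the fit, were, for 2HS against 2NS, 210 and 389 in nuclear RNA, 313 and 314 in poly(A)+ RNA, 865 and 864 in TRAP RNA, 0 and 0 in Ser2P, 0 and 0 in H3K4me3, 0 and 0 in H3K27me3, 16 and 0 in H3K14ac and 29 and 29 in H2A.Z. For 9HS they were 676 and 1530 in nuclear RNA and 987 and 979 in poly(A)+ RNA. For 1R against 2HS they were 289 and 98 in nuclear and 383 and 384 in poly(A)+ RNA, and against 2NS 12 and 1, and 288 and 290. For 9NS against 2NS they were 7 and 106 in nuclear and 296 and 295 in poly(A)+ RNA. For 9 h minus 2 h they were 3 and 17 in nuclear RNA, 659 and 623 in poly(A)+ RNA and 41 and 41 in H3K14ac. For poly(A)+ minus nuclear RNA they were 4 and 2 at 2 h and 80 and 300 at 9 h, and for TRAP minus poly(A)+ RNA 118 and 112. With the RNA columns rescaled before the pseudocount, limma's calls of that size for 2HS were 276 in nuclear RNA, 364 in poly(A)+ RNA and 864 in TRAP RNA, for 9HS 438 in nuclear and 1090 in poly(A)+ RNA, and for 1R 441 and 338 against 2HS and 12 and 264 against 2NS. For 9NS against 2NS they were 7 and 254, for 9 h minus 2 h 0 and 416, for poly(A)+ minus nuclear RNA 11 at 2 h and 4 at 9 h, and for TRAP minus poly(A)+ RNA 42. Of 370 list tests 128 were called at the preset and 34 with an estimated correlation.

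Leaving out each library in turn, the calls of at least 2-fold for 2HS ranged from 105 to 222 in nuclear RNA, 280 to 390 in poly(A)+ RNA, 843 to 1111 in TRAP RNA, 1 to 1848 in H3K27me3, 590 to 867 in H3K9ac, 0 to 43 in H3K14ac and 24 to 602 in H2A.Z, and stayed at 0 in Ser2P and H3K4me3. For 9HS they ranged from 233 to 567 in nuclear RNA, 825 to 1330 in poly(A)+ RNA, 2225 to 2497 in H3K9ac and 358 to 1221 in H3K14ac. Against 2HS, 1R had 82 to 566 in nuclear and 351 to 436 in poly(A)+ RNA, and 2R 1270 to 1621 in TRAP RNA. Against 2NS these were 0 to 34, 258 to 349 and 135 to 350. For 9NS against 2NS they were 5 to 9 and 239 to 472 in nuclear and poly(A)+ RNA. For 9 h minus 2 h they were 0 to 4 in nuclear RNA, 413 to 1155 in poly(A)+ RNA, 186 to 728 in H3K9ac and 0 to 109 in H3K14ac, for poly(A)+ minus nuclear RNA 0 to 25 at 2 h and 6 to 261 at 9 h, and for TRAP minus poly(A)+ RNA 48 to 334.

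Leaving out a library was also set against limma's count of that size with all libraries. Libraries that moved this count by over 1.5 times are named by group and depth in M reads. For nuclear RNA of 2HS they were 2HS 3.04 (112) and 2.12 (105) and 2NS 3.02 (126) and 2.22 (111). For nuclear RNA of 9HS they were 9HS 2.36 (344) and 2.18 (321) and 9NS 6.40 (281), 4.21 (233) and 3.76 (260). In H3K27me3 they were 2HS 5.17 (1848) and 8.47 (1) and 2NS 8.76 (11) and 4.36 (51), in H3K14ac of 2HS 2HS 12.0 (43) and 3.55 (2) and 2NS 8.77 (0) and 5.42 (10), in H3K14ac of 9HS 9HS 11.7 (1221) and 8.36 (358), and in H2A.Z 2HS 10.0 (602) and 5.48 (120). For nuclear RNA of 1R against 2HS they were 1R 8.84 (566) and 2HS 3.04 (110) and 2.12 (82), and against 2NS 1R 8.84 (34) and 1.05 (5) and 2NS 15.5 (4) and 2.22 (0). For TRAP RNA of 2R against 2NS they were 2R 5.10 (135) and 4.35 (350), and for poly(A)+ RNA of 9NS against 2NS 9NS 9.35 (472). For 9 h minus 2 h they were 2HS 12.2 (1000), 9NS 12.1 (413) and 9.35 (1155) in poly(A)+ RNA, 2NS 10.6 (186) and 9HS 11.7 (287) in H3K9ac, and 2HS 3.55 (6), 9HS 11.7 (109) and 8.36 (0), 2NS 8.77 (0) and 5.42 (0) and 9NS 7.05 (0) and 6.55 (0) in H3K14ac. In nuclear RNA 10 of the 12 libraries gave 0. In poly(A)+ minus nuclear RNA at 2 h 8 of the 12 gave 0, and at 9 h and in TRAP minus poly(A)+ RNA most libraries moved the count by over 1.5 times without ending it.

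Among the 464 genes 2-fold apart in poly(A)+ RNA, correlations of the 2 h changes across genes were 0.836 for nuclear and poly(A)+ RNA, 0.817 for nuclear and TRAP RNA, 0.794 for nuclear RNA and Ser2P, 0.868 for poly(A)+ and TRAP RNA, 0.725 for poly(A)+ RNA and Ser2P and 0.733 for TRAP RNA and Ser2P. These genes were picked for a large change in the same poly(A)+ values. Leaving out genes with small changes can raise a correlation by construction. The values are therefore no measure of closer agreement than over all genes. The share of 2HS ATAC peaks met by 2NS peaks was 75.7% for equal numbers of top-scoring peaks and 36.6% for reciprocal overlap. That of 9HS peaks met by 9NS peaks was 78.2% and 66.4%.

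List medians that changed sign were, for auxin and growth genes in poly(A)+ RNA of 1R against 2NS, 0.20 (pseudocount of 0.1 RPKM), 0.11 (no filter), 0.16 (quantile normalization) and 0.16 (rescaled), and for nuclear photosynthesis genes in poly(A)+ minus nuclear RNA at 2 h -0.0698 (pseudocount) and -0.0928 (rescaled). With no filter they were -0.21 for glycolysis and fermentation enzymes in poly(A)+ RNA of 9HS, 0.18 for photosynthesis in poly(A)+ RNA of 1R against 2HS, 0.11 for clock genes in the 9 h minus 2 h effect of poly(A)+ RNA, 0.22 and 0.16 for core hypoxia genes and glycolysis in poly(A)+ RNA of 9NS against 2NS, -0.75 for dark and sugar starvation genes in poly(A)+ minus nuclear RNA at 9 h and -0.0027 for glycolysis in TRAP minus poly(A)+ RNA. Quantile normalization gave 0.0277 for photosynthesis in nuclear RNA of 1R against 2NS and 0.0534 for heat shock genes in poly(A)+ RNA of 9NS against 2NS, where rescaling gave 0.10. LHCB1.1 in poly(A)+ minus nuclear RNA at 9 h was at 0.91 with quantile normalization.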

Other observations

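The tests of the hypothesis in this part were chosen after the results were seen. Cell cycle genes had a median change of 1.03 in nuclear RNA of 9HS against 9NS, with 1 of 15 resolved members higher and 3 adjusted over the list alone (adjusted p = 0.0308 with an estimated correlation), and CDC20.1, an activator of the anaphase-promoting complex, rose in poly(A)+ RNA, by 1.85 ± 0.19 rescaled to the same protein-coding total (adjusted p = 5.07e-07). Root endodermis markers had 2 of 5 resolved members lower in poly(A)+ RNA of 9HS, CASP1 (-1.47, adjusted p = 7.23e-04) and CASP2 (-0.75, adjusted p = 9.18e-04), which build the Casparian strip (median -0.35; adjusted p = 0.198 with an estimated correlation). Of guard cell markers 2 of 2 resolved members rose there when rescaled, FMA by 0.74 ± 0.22 (adjusted p = 0.0142) and MYB60 by 0.72 ± 0.19 (adjusted p = 0.00662), from levels of 2.07 and 4.35 RPKM in 9NS. Root hair cell markers fell in 4 of 6 (median -0.89; adjusted p = 0.167 with an estimated correlation), RHS13 (-1.76, adjusted p = 1.36e-05) among them. In 1R against 2NS 5 of 6 fell, or 3 rescaled (median -1.16; adjusted p = 0.128 with an estimated correlation), with PRP3 at -1.42 (adjusted p = 1.75e-05) and RHS19 at -1.40 (adjusted p = 2.56e-05).

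Mitochondrial retrograde and oxidative genes gained H3K9ac in 8 of 10 at 9 h (median 0.74; adjusted p = 0.188 with an estimated correlation), while their poly(A)+ RNA had 3 of 9 lower (median -0.67; adjusted p = 0.48 with an estimated correlation). In TRAP RNA of 2R against 2NS 3 of 8 rose (median 0.94; adjusted p = 0.37 with an estimated correlation). Polycomb target regulators had a median of -0.22 in H3K14ac of 9HS (adjusted p = 0.0457 at the preset and 0.583 with an estimated correlation), and at 2 h PI, a floral identity gene in that list, gained H3K9ac (0.79, adjusted p = 0.00423). The core hypoxia genes AT4G10270 and AT5G10040, AT5G51190 of the rapid wound and defence list and the flowering repressor FLC were listed at 0 in every column.

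A hypothesis from these data is that hypoxia for 9 h opposed the change that untreated seedlings showed between 2 h and 9 h. It was tested on genes 2-fold apart in poly(A)+ RNA of 9NS against 2NS, in libraries of other assays. In H3K9ac of 9HS against 9NS, the 420 higher genes had a median of -0.81, below all matched random lists, and 192 lower genes had 0.07, at percentile 98.7 of theirs. In nuclear RNA of 9HS against 9NS, 410 of the higher genes had a median of -1.14 and 180 of the lower genes 1.48, above all matched random lists. H3K14ac gave -0.10 and 0.00, at percentiles 0 and 50.5. Across all genes tested, which are not independent replicates, the changes correlated with those in untreated poly(A)+ RNA at -0.135 for H3K9ac, -0.229 for nuclear RNA and 0.111 for H3K14ac. The H3K9ac change of 2HS against 2NS was -0.11 and -0.10 for the same genes, at percentiles 0 and 0.02, so their H3K9ac differed from that of matched genes at 2 h too; the cause was not tested. The values for higher and lower genes in H3K9ac and nuclear RNA go the way of the hypothesis, small as the 0.07 is. The lower genes and the correlation in H3K14ac do not. H3K9ac itself was 2-fold higher at 94 and lower at 47 of 26493 genes in 9NS against 2NS. In 9HS against 9NS these numbered 1134 and 1152. H3K9ac thus had few untreated changes of that size for hypoxia to oppose. Nuclear and poly(A)+ RNA may come from the same seedlings.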
